A study of Apis mellifera with 6 samples.

How the data were processed

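RNA of the hypopharyngeal gland, the paired head gland of worker honeybees (Apis mellifera) that secretes brood food, was sequenced in 6 libraries from 6 colonies, with 2 colonies in each of 3 groups. Per the labels, the Honey group received honey alone and had caged queens, the Pollen group received honey and rape pollen and had caged queens, and the Brood group received honey and rape pollen and had freely laying queens. Libraries were made from 3 ug of total RNA with the NEBNext Ultra kit, per the labels' protocols, and whether counting used strand is not given in the sources used here. The aligner, the counting tool, the gene annotation and the name of the genome build are likewise not given in the sources used here. The ages conflict. The series text gives 9 days for all bees, whereas the sample labels give 9 and 10 days for Pollen 1 and 2, 11 and 12 days for Honey 1 and 2, and 13 and 14 days for Brood 1 and 2. If the sample labels hold, age and group cannot be separated by group means.

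Each deposited file listed 10704 gene models, of which 10344 had an ID made of a gene number and 360 were gene models added by the authors, behind a header line repeated inside the file. Per the file headers, the authors gave a raw fragment count, a normalized count, an FPKM value and a length for each model. The raw counts were whole numbers. From the values, the authors' normalized count, treated here as a signal, was the raw count multiplied by 1 factor per library for 68.1% to 69.2% of models within 0.02 fragments, and the raw count was higher for the others, as if fractional estimates had been rounded up. The deposited FPKM values were the normalized counts divided by length and by 1 total that was nearly the same in all 6 libraries, so their sums differed between libraries. Library totals of raw counts ran from 2764870 to 4153354 fragments. A count of 3 fragments, the upper limit that a count of 0 allows, corresponded to 0.722 to 1.09 CPM of the raw total. No column belonged to other samples. Replicates were not duplicates of each other, since their counts differed by 27.3 to 117 times the variance expected from sampling.

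The raw counts were tested. The planned test had assumed FPKM, with the count test named for the case that the files hold counts, so that case applied and limma on FPKM became an alternative. Genes were filtered with filterByExpr (minimum count 10), which kept 6943 models, scaled by TMM, and compared with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest). All 6 libraries entered 1 fit with 3 group means and 3 residual degrees of freedom, with a two-sided test and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Every adjusted p in the text comes from this test unless another is named. CPM values, which are fragments scaled to a common library size, used the TMM-scaled totals. The SE of a log2 change was its size divided by the square root of its quasi-likelihood F. The 95% intervals of fold changes were built on this SE. Both therefore restate the test and are not standard errors of the fitted coefficient. Binomial intervals of shares cover counting error only. The colonies were separate per the labels, so the spread between libraries includes that between colonies, but 2 against 2 libraries cannot reach an exact permutation p under 0.333. Groups of 2 were too small for a test for outlying libraries and for counts of other splits.

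The gene IDs could not be turned into names. None of the 10704 IDs matched the 12398 genes of the reference table, whose assembly is Amel_HAv3.1, and 0 matches were made by any identifier. The 30 gene lists fixed before the data were examined, the rule for naming genes by descriptive name, and the share taken by royal jelly protein genes were therefore not used here. In their place, 2 models that rose and 2 that fell are given by ID for each comparison. In each direction, 1 was the called model with most fragments. The other had the largest change among called models with 1000 or more fragments in each library of the higher group. Both required that all libraries of 1 group lie above those of the other, and models added by the authors could not be picked. This rule, and all sets defined by position or length, were chosen after the data were seen. Tests of 6 sets, adjusted together, used camera in limma 3.58.1 with a preset correlation and with an estimated correlation. The sets were the mitochondrial loci, the other models added by the authors, the models on unplaced scaffolds and the tandem region. The rest were the shortest and longest deciles of model length. Coordinates are those of the files. Linkage groups follow the sequence identifiers in the files.

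There were 4 models listed at exactly 0 in some libraries beside 10000 or more fragments in another, and 2 models that overlap them and were at 0 in the same libraries. Their values are given per library and they were left out of the main sums over the tandem region, beside which sums with them are given. They stayed in the test and in the counts of calls, but not in the counts of changes over 10-fold or among the models given by ID. The principal components and the quintiles and correlations by model length also leave them out. So do the pairs of neighbouring models and the comparison of the changes with pollen and with brood.

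The scripts were tested on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. For Pollen vs Honey, on 6568 genes, 12.4% of the 2-fold and 84.5% of the 4-fold changes were recovered, with 14 false calls among 108. For Brood vs Pollen, on 6624 genes, 5.21% and 77.3% were recovered, with 3 false calls among 83. For Brood vs Honey, on 6612 genes, 7.53% and 70.8% were recovered, with 8 false calls among 83. These shares hold for simulated data in which few genes changed.

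Alternatives tried were DESeq2 1.42.0 (size factors and Wald test), no filter, only the libraries compared, the replicate number as a block, age as a covariate, other settings of the empirical Bayes prior, leaving out each library, and limma on FPKM with other pseudocounts, filters and scalings. Those chosen after seeing the data were limma with a pseudocount of 1 in place of the planned main test, library totals as the only scaling, leaving out the models listed at 0, summing the tandem region with them or without its most abundant model, removal of each library's length trend, and a test against a 2-fold change. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.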

Results

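Gene expression was measured by RNA sequencing in the hypopharyngeal glands of worker honeybees from 6 colonies, in 3 groups of 2 libraries. The Honey group had honey alone and caged queens, the Pollen group had honey with rape pollen and caged queens, and the Brood group had honey with rape pollen and laying queens. The libraries held 4153354 and 3546705 counted fragments in Pollen 1 and 2, 4120794 and 2764870 in Honey 1 and 2, and 3459632 and 3525248 in Brood 1 and 2. The sample labels also give the 3 groups different ages, in conflict with the series text, so a difference between groups is not separated from age.

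The share of RNA taken by the 10 most abundant gene models was lowest in Honey and highest in Brood. In each library the 10 most abundant held, on average, 27.4% ± 0.860 of fragments in Honey, 51.7% ± 2.63 in Pollen and 68.0% ± 1.58 in Brood (SD, n = 2 each). These shares include models that were listed at 0 in other libraries. Among them, 1 had 506115 fragments in Pollen 1 and 0 in Pollen 2. Another had 337402 and 347627 in Pollen 1 and 2 and 0 in Brood. Shares without such models were not computed. The model gene5402, on linkage group 6 at 15407272 to 15408113 with a length of 237 bases, was the most abundant in all 6 libraries. It held 12.6% ± 0.918 of fragments in Honey, 15.3% ± 0.904 in Pollen and 24.3% ± 1.22 in Brood (SD, n = 2 each). Fewer models had any fragment in Brood (8012.5 ± 170) than in Pollen (8577 ± 148) or Honey (8774 ± 199; SD, n = 2 each). However, the 10 most abundant models left the smallest share of fragments for all other models in Brood. Depth was not varied, so this count cannot separate fewer expressed models from fewer fragments left to detect them. A second concentration was a tandem region on linkage group 11, from 2563562 to 2614036, where 8 models on the plus strand lie in 50475 bases and 7 of them reached 10000 or more fragments in a library. The next densest stretch had 2 such models. The 6 models of this region with values in all groups held 0.681% ± 0.135 of fragments in Honey, 11.3% ± 2.54 in Pollen and 33.9% ± 2.72 in Brood (SD, n = 2 each). With the other 2 models, which were listed at 0 in some groups, the shares were 2.18% ± 0.754 in Honey, 20.3% ± 3.72 in Pollen and 33.9% ± 2.72 in Brood (SD, n = 2 each).

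**Figure D1:**
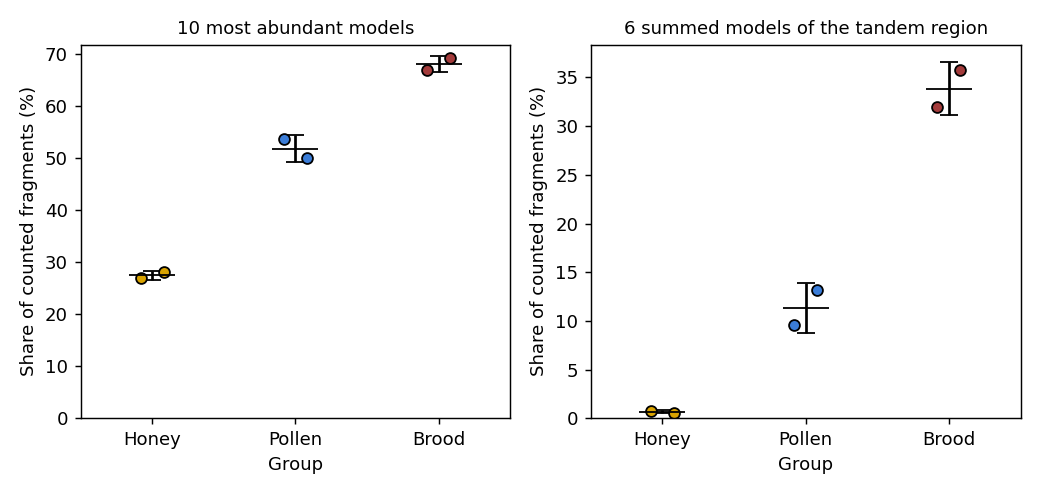
Share of counted fragments (%) held by the 10 most abundant models of each library (left) and by 6 summed models of the tandem region on linkage group 11 (right). Points are libraries, and bars are group means with SD (n = 2). The mean share of the 10 most abundant models was 27.4% in Honey, 51.7% in Pollen and 68.0% in Brood.

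Libraries of a group resembled each other more than those of other groups. The correlation of log2 CPM across genes, which are not independent replicates, was 0.939 to 0.968 within groups, 0.894 to 0.920 between Pollen and Honey, and 0.689 to 0.717 between Brood and Honey libraries. The first principal component carried 70.5% of the variance and set the Brood libraries apart, and the second carried 13.4% and set Pollen apart from Honey.

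**Figure D2:**
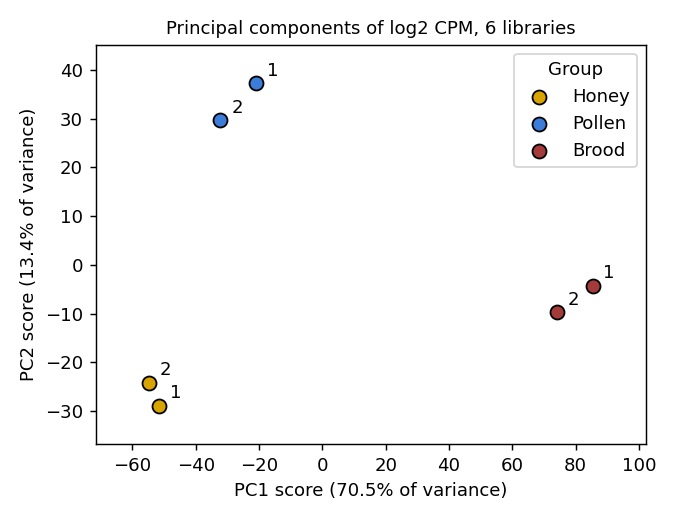
Scores of the 6 libraries on the first principal component (70.5% of variance) and the second (13.4%), from log2 CPM. Points are coloured by group and numbered by replicate. The 2 libraries of each group lie together.

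The comparison of Pollen with Honey concerns nutrition, since both groups had caged queens. In the tandem region, the 6 models with values in all groups went in sum from 4035 ± 253 CPM in Honey to 123944 ± 5682 CPM in Pollen (SD, n = 2 each), a 30.7-fold difference, and all 6 were called higher. Of these, the model at 2592827 to 2593803 was near the floor, with 1 and 0 fragments in Honey. It had 25 and 12 in Pollen and 57 and 65 in Brood, and is counted among the 6 in each comparison. Summed over all 8 models the difference was 17.6-fold, and 1 of the left-out models went from 74052 and 27774 fragments in Honey to 0 in Pollen. The other left-out model had more fragments in Pollen than in Honey. Within the region, gene8627, at 2563562 to 2566839, rose 205-fold (95% interval 58 to 721; log2 change 7.68, SE 0.84; adjusted p = 0.000319, edgeR). Its log2 change was 6.73 without Pollen 1 and 8.24 without Pollen 2. The model gene13370, on an unplaced scaffold at 35 to 1903, rose 188-fold (72.3 to 491), from 15.4 ± 1.27 to 2919 ± 384 CPM (SD, n = 2 each). Among the models that fell, gene4810 on linkage group 6 at 189128 to 190923 was 8.21-fold lower in Pollen (3.95 to 17.1; log2 change -3.04, and -3.70 without Pollen 2). It lies inside gene4809, at 175095 to 198140 on the opposite strand, which was 8.87-fold lower (5.15 to 15.2). Their fragments may not be separable, because strand use in the counting is not stated.

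Of 6943 models tested, 428 differed between Pollen and Honey by edgeR's quasi-likelihood test, with 300 higher and 128 lower in Pollen. These include 5 of the models listed at 0 in some libraries, 4 higher and 1 lower. Leaving those out, 42 were more than 10-fold higher and 13 more than 10-fold lower. The count depended most on the Honey libraries, although leaving out either Pollen library lowered it too. It was 134 without Honey 1 (74 higher and 60 lower) and 185 without Honey 2. In limma on FPKM it was 65 to 256, depending on the pseudocount, filter and scaling. When libraries were scaled by their totals alone, 136 models were higher and 2312 lower, since the median model then shifted by -0.89 on the log2 scale.

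The comparison of Brood with Pollen concerns brood, since both groups had pollen. The same 6 models of the tandem region were higher again in sum, from 123944 ± 5682 to 513294 ± 10824 CPM (SD, n = 2 each), a 4.14-fold difference. It was 2.69-fold without the model with most fragments and 2.30-fold over all 8 models, and the models diverged. Of the 6, there were 4 called higher and 1 called lower, the model at 2581588 to 2584699 with a log2 change of -4.34 (SE 0.53), and 1 was not called. Both left-out models were listed at 0 in Brood. Within the region, gene8627 rose 14.4-fold (95% interval 5.01 to 41.1; log2 change 3.84; adjusted p = 0.00121, edgeR), with a log2 change of 4.78 without Pollen 1 and 3.29 without Pollen 2. The model gene8969, on linkage group 11 at 11123138 to 11132857, rose 80.4-fold (43.6 to 149), from 15.6 ± 1.99 to 1261 ± 180 CPM (SD, n = 2 each). The model gene10274, on linkage group 13 at 7932097 to 7935133, was 38.6-fold lower in Brood (14.6 to 102), at 74204 ± 23732 CPM in Pollen and 1923 ± 409 CPM in Brood (SD, n = 2 each). The model gene5941, on linkage group 7 at 7421481 to 7427444, was 98.4-fold lower (37.7 to 257), with only 42 and 10 fragments in Brood 1 and 2. Its log2 change was -6.62, and it was -8.09 without Brood 1 and -5.89 without Brood 2.

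**Figure D3:**
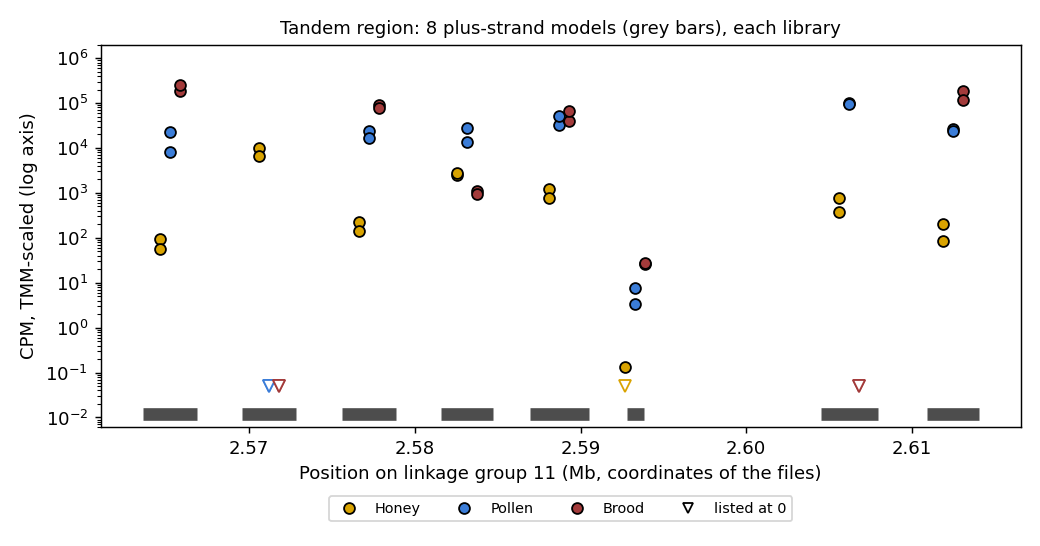
The tandem region on linkage group 11. The x axis is position in Mb and the y axis is TMM-scaled CPM on a log axis, with points for each library coloured by group, grey bars for the 8 models and open triangles for values listed at 0. The summed CPM of the 6 models with values in all groups was 4035 in Honey, 123944 in Pollen and 513294 in Brood.

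There were 3359 models that differed between Brood and Pollen, 1553 higher and 1806 lower, with 2 models listed at 0 among the lower. Leaving those out, 165 were more than 10-fold lower against 37 more than 10-fold higher. Tested against a change of 2-fold or less, 357 were higher and 806 lower. The direction depended on the length of the model. In the shortest quintile of model length, 628 were called higher and 59 lower, and in the longest quintile 34 were higher and 875 lower. With each library's length trend removed, 2069 models were called, 1132 higher and 937 lower. Scaling by library totals gave 553 higher and 2253 lower.

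The comparison of Brood with Honey combines pollen and brood. The 6 models of the tandem region were 127-fold higher in sum in Brood, 73.5-fold without the model with most fragments and 40.6-fold over all 8 models, with 5 of the 6 called higher and 1, again the model at 2581588, called lower. Both left-out models had fragments in Honey and were listed at 0 in Brood. The model gene13370 was 5400-fold higher in Brood (95% interval 1720 to 17000; log2 change 12.40, SE 0.76; adjusted p = 1.38e-06, edgeR), at 83650 ± 879 CPM against 15.4 ± 1.27 CPM in Honey (SD, n = 2 each). The most abundant model, gene5402, was 4.85-fold higher (1.90 to 12.4; log2 change 2.28; adjusted p = 0.00810, edgeR), but only 16 of 24 alternatives kept this call. The call was lost when either Brood library was left out (adjusted p = 0.113 without Brood 1 and 0.0735 without Brood 2, edgeR), although the log2 change was 2.16 and 2.37, and when the length trend was removed, which left a log2 change of 0.51. With library totals the log2 change was 0.94. The call was also lost in limma on FPKM with a pseudocount of 0.1 (adjusted p = 0.0843) or 0.5 (0.0562), without a filter (0.394) and after quantile normalization, and with age as a covariate. The log2 change was 2.01 in the limma fits with those pseudocounts and without a filter, and 2.46 with age. Of the models that fell, gene202 on linkage group 1 at 3291823 to 3297146 was 4.45-fold lower in Brood (2.14 to 9.26; adjusted p = 0.00268, edgeR), and this call was lost without Brood 2. It overlaps 1 model on the opposite strand. The model gene5941 was 99.9-fold lower (38.3 to 261; log2 change -6.64), and its log2 change was -8.12 without Brood 1 and -5.92 without Brood 2.

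In all, 3969 models differed between Brood and Honey, 1971 higher and 1998 lower, with 2 models listed at 0 in each direction. With the length trend removed 2673 were called, 1473 higher and 1200 lower, and 19 of the 3969 were called in the opposite direction. Scaling by library totals moved the median by -1.35 on the log2 scale and gave 305 higher and 3707 lower. In limma on log2(FPKM + 1) the split was 1394 higher and 2177 lower, and for Brood vs Pollen 1048 higher and 1803 lower. The same test gave 1975 higher and 1738 lower, and 1621 higher and 1426 lower, with FPKM as deposited, and 1719 and 1690, and 1367 and 1383, after quantile normalization. The sum over the 6 models of the tandem region kept its direction with library totals, at log2 changes of 4.05, 1.59 and 5.65 for Pollen vs Honey, Brood vs Pollen and Brood vs Honey, against 4.94, 2.05 and 6.99 with TMM. With the ages of the sample labels as a covariate, 33, 19 and 1815 models were called in the same order. Of the models given by ID, gene13370 in both comparisons and gene5941 in Brood vs Honey kept their calls with that covariate. The others lost theirs while their log2 changes stayed in the same direction, for example 6.39 for gene8627 in Pollen vs Honey and -7.02 for gene10274 in Brood vs Pollen. Of the models called without the covariate, 424 of 428, 3163 of 3359 and 3949 of 3969 kept their direction with it. With the length trend removed, the log2 change was 7.10 for gene8969 in Brood vs Pollen, and 11.71 for gene13370 and -1.50 for gene202 in Brood vs Honey. For gene202 it was -2.15 in the main fit, -3.50 with library totals and -3.66 in limma on FPKM after quantile normalization.

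The change with model length was weaker between Pollen and Honey. Across genes, Spearman's correlation of the log2 change with length was -0.27 for Pollen vs Honey, -0.56 for Brood vs Pollen and -0.59 for Brood vs Honey. The median log2 change of the shortest quintile was 0.36, 1.00 and 1.40 in the same order, and that of the longest quintile was -0.22, -1.37 and -1.53.

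**Figure D4:**
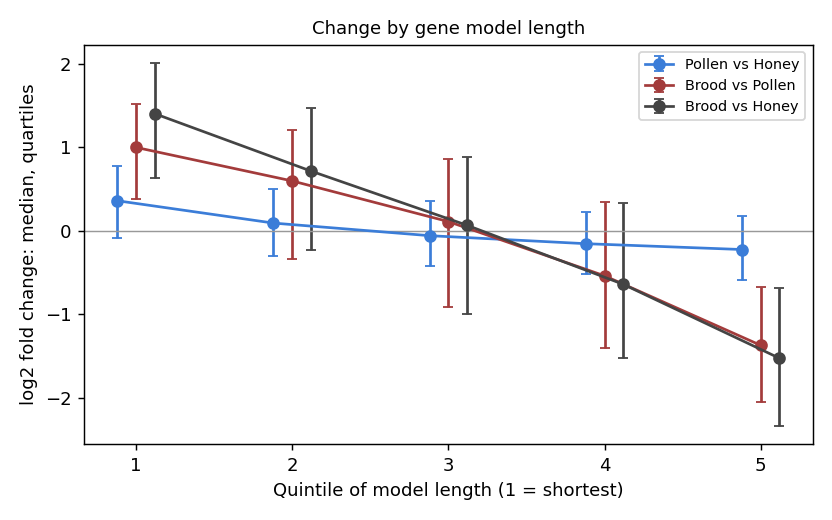
Median log2 fold change, with quartiles as bars, in quintiles of gene model length from shortest (1) to longest (5) for the 3 comparisons. In Brood vs Honey the median ran from 1.40 in the shortest quintile to -1.53 in the longest.

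The changes with pollen and with brood were compared gene by gene, although both comparisons use the Pollen libraries with opposite sign. Without the models listed at 0, 296 models rose from Honey to Pollen and 127 fell. Of the 296, 64 rose again in Brood, where independent lists would share 66.3, and 118 fell, where independent lists would share 77.0. Of the 127 that fell from Honey to Pollen, 53 fell again (33.02 for independent lists) and 17 rose (28.4). Unchanged groups with the same shared libraries gave at most 1 shared call in 20 simulations, but these made at most 4 calls each and so set no level for overlaps between lists with real changes. The correlation of the log2 changes across 6938 models was 0.061, with a covariance of 0.0657. In 100 simulations of unchanged groups, the mean correlation was -0.490 and the mean covariance -0.0946. Without changes, the shared Pollen libraries alone fix a negative correlation. These simulations therefore set no level for the correlation between groups that differ. Part of any difference from independent lists may come from the shared libraries. Both changes also fell with model length (Spearman's correlation -0.27 for Pollen vs Honey and -0.56 for Brood vs Pollen). Neither the overlaps nor the correlation of the changes was adjusted for length, so a shared length trend was not separated from a common change.

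Some abundant models were listed at exactly 0 in whole groups. In the tandem region, the model at 2569547 to 2572833 had 74052 and 27774 fragments in Honey 1 and 2 and 0 in all Pollen and Brood libraries. The model at 2604510 to 2607949 had 337402 and 347627 fragments in Pollen, 5802 and 1616 in Honey, and 0 in both Brood libraries. A model on linkage group 6 at 4035400 to 4081096 had 506115 fragments in Pollen 1, 26420 and 5336 in Brood 1 and 2, and 0 in Pollen 2 and both Honey libraries. In the same order, a model at 3898061 to 4069678 had 23356, 44 and 3 fragments, a model at 4078213 to 4088611 had 700, 166 and 230, and a model at 4022216 to 4030057 had 10, 3 and 15, and all were at 0 in those libraries. These zeros are given as listed, with no fold change.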

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

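The alternatives chosen after seeing the data were limma on log2(FPKM + 1), library totals only, leaving out the models listed at 0, summing the tandem region with them or without its most abundant model, removal of the length trend and the test against a 2-fold change. The number of models that differed between Pollen and Honey (428) became 795 without the filter, 33 with age as a covariate, 2448 with library totals, 109 against a 2-fold change, and, with limma on FPKM, 206 with a pseudocount of 1, 93 with 0.1, 170 with 0.5, 65 without a filter, 210 at an FPKM of at least 5, 154 with FPKM as deposited and 256 after quantile normalization. Brood vs Pollen (3359) became 19 with age as a covariate, 2184 with limma at an FPKM of at least 5 (2851 with limma at the lower filter), 2069 with the length trend removed and 1163 against a 2-fold change. Brood vs Honey (3969) became 1815 with age, 2582 with limma at an FPKM of at least 5 (3571 at the lower filter) and 2067 against a 2-fold change. The 2-fold test asks for more, and age was estimated only from the 1-day gaps within groups and extrapolated; the other causes were not tested. Leaving out single libraries gave 134 to 549, 2306 to 3146 and 3031 to 4029 models, with a lone library assumed to vary like the other groups. With the replicate number as a block the counts were 435, 3313 and 3901. By the sample labels, replicate 2 was 1 day older than replicate 1 in every group. Beside group means, the block and the age covariate are therefore the same fit, read without and with extrapolation over days. The deviations of same-numbered libraries correlated at only -0.103, 0.040 and 0.142 between groups, so little was shared by replicate number or by that 1-day step. The correlation of the 2 changes was 0.212 with Pollen 1 in the first and Pollen 2 in the second comparison, and 0.060 with the 2 exchanged, against 0.061. Of the single models and region sums, 289 values were classed as the same, 18 lost the threshold and 11 moved. For a single model, the same meant that direction and side of the threshold were kept. Region sums have no p, so for them it meant the same direction and a shift below the SD within groups. All 11 that moved were region sums. For gene5402 quantile normalization gave a change of 0, which that method fixes for a model ranked first in every library. Not run for lack of gene names were the gene list alternatives, the royal jelly protein share with its alternatives, and scaling without those genes. Depth itself was not varied.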

Other observations

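All sets and tests in this part were chosen after the results were seen. Neighbouring models had the same call more often than in shuffles of the calls. Between Pollen and Honey, 52 of 6777 adjacent pairs had the same call, against a mean of 14.7 and a highest value of 26 in 1000 shuffles. The numbers were 1045 against 797 for Brood vs Pollen and 1334 against 1106 for Brood vs Honey. Each gave p = 0.001 by these shuffles, the smallest the permutations can give. The shuffles did not hold model length, and overlapping models and the tandem region stayed among the pairs. Shared fragments or similar lengths of neighbours were therefore not separated from a common change. The 4 mitochondrial loci were all called higher in Brood than in Honey, and held 0.910% ± 0.252 of fragments in Brood and 0.277% ± 0.0541 in Honey (SD, n = 2 each), and as a set they passed with a preset correlation (adjusted p = 0.0114, camera) but not with an estimated correlation (adjusted p = 0.272). The mitochondrial loci were themselves gene models added by the authors and were left out of the set of such models. Of the 289 other tested gene models added by the authors, 47 were higher and 122 lower in Brood than in Honey (adjusted p = 0.00382 with a preset and 0.0493 with an estimated correlation, camera). In Brood vs Pollen 36 were higher and 107 lower (adjusted p = 0.00237 preset and 0.0520 estimated), and in Pollen vs Honey 14 were higher and 9 lower (0.598 and 0.515). Of 428 models on unplaced scaffolds, 169 were higher and 89 lower in Brood than in Honey (adjusted p = 0.0115 preset and 0.272 estimated). The longest decile of models was lower in Brood than in Honey (adjusted p = 4.2e-33 preset and 0.00799 estimated), and the shortest decile was higher only with a preset correlation (1.25e-21 and 0.149). The 6 models of the tandem region were tested too, but that set had lost the models listed at 0 and so its test is not used. It passed in Pollen vs Honey (adjusted p = 3.21e-27 preset and 0.00894 estimated, camera) and in Brood vs Honey (2.66e-08 and 0.0302, camera). In Brood vs Pollen it did not pass (adjusted p = 0.0600 preset and 0.283 estimated, camera).

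Models listed at 0 beside many fragments were first weighed as a technical failure: it may be that estimates failed for whole loci in some libraries. On linkage group 6, 2 models prompted this, and only 1 further overlapping model had 100 or more fragments in each of the other 3 libraries. That 1 model was at 0 in the same 3 libraries, which is too few to decide. Of all 1177 models with 100 or more fragments in each of the other libraries, 2 were at 0 in the same 3 libraries. Both lie at this locus, and 1 of them had prompted the test. For the 2 models of the tandem region, the number expected from the median change of the other models exceeded the largest number listed for any model (868998) in all 6 values at 0, but the range of expected numbers reached below it, so a limit of the authors' counting cannot be told apart from silence or from fragments assigned to a near-identical copy. None of the other 54 models that reached 10000 fragments fell below 61 in a library.

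Brood libraries had lower values for long models and higher values for short ones. A difference in abundance by length was argued against, since the rank correlation between change and length in Brood vs Pollen was -0.43 or lower in each quintile of abundance. Variation from library to library irrespective of group was argued against as well, since the smallest gap in slope between a Brood library and another was 5.06 times the largest gap between replicates. With each library's mean trend on the listed model length removed, 1676 of the 3359 calls were still called in the same direction. The others were no longer called or, for 4 models, were called in the opposite direction. That mean trend was therefore not the whole source of the calls. A bias that differs between models of like listed length would remain, so a length bias as the whole cause was not decided. RNA integrity or fragment selection that went with the group, and a biological difference between the groups, stay open and were not tested, because the values hold no coverage along transcripts.

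As a hypothesis, it may be that the region holds the major royal jelly protein genes, which encode the main secreted products of this gland. In the reference table (Amel_HAv3.1), 9 genes with Mrjp symbols lie on 1 linkage group within a stretch of 10 coding genes. The best alignment of the region's 8 model starts to that stretch matched 6 within 250 bases, 5 of them to genes with Mrjp symbols. However, 1 of the 24796 alignments tried matched as many elsewhere. Within 500 bases, 6 matched there and 7 elsewhere. Alignments were tried on every sequence of the reference table and in both directions. The region's own linkage group was not used, so a match elsewhere may lie on another linkage group. Spacing alone therefore did not single out this stretch, and the hypothesis stays undecided. The tolerance of 500 bases was the one first intended, and 250 was added once the spacing was known.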
